A study of Homo sapiens with 40 samples.

How the data were processed

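The deposited per-gene tables give, per the file headers, whole read counts for each Entrez gene, scaled counts (RPM), counts over introns and gene coordinates. The counts column was analysed, and blanks were read as 0. RPM was used only to check the counts, and intron counts were not used here. Per the submitters' processing notes the tools were CASAVA 1.8.2, BWA, SAMtools and GATK, without a role given for each. The gene counter, its strand setting and the genome build are not given in the sources used here.

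Each table holds 25619 genes, joined on Entrez ID because 10 tables hold 26 gene symbols turned into dates. Of these genes, 25478 were kept and 141 genes of the Y chromosome or of XIST and TSIX were left out before scaling. A further 101 genes have no symbol. The 194 immunoglobulin genes were kept in the totals, although variable segments share reads with the locus entries. The 13 mitochondrially encoded protein genes are absent, so 28 of 29 gene lists were tested. HLA, immunoglobulin, T cell receptor and uncharacterised genes were tested and never named.

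Counts were scaled by TMM, filtered by filterByExpr and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) under R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Comparison runs used DESeq2 1.42.0, and lists were tested with limma 3.58.1. The drug arms were fitted together, 28 libraries and 7 sets, with the set number as a block. Control culture against 0 h was fitted with the 6 sets that have both, again with the set as a block. Myeloma at 0 h against normal plasma cells had no block. The block is a choice that decides the drug results: without it 0 genes were called in every drug comparison. These choices, the gene lists and the study genes were fixed before the data were examined. No batch, dose or culture time was used here.

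Pairing comes from the sample titles, which lay the arms out under a set number. It was checked by correlating gene levels after removing arm means: cultured libraries of 1 set had r from 0.759 to 0.940 (median 0.865) and other pairs from -0.598 to 0.320, and 28 of 28 were nearest to their own set. Control culture and 0 h libraries of 1 set had r from 0.526 to 0.698 (median 0.578) and other pairs from -0.483 to 0.299, with 12 of 12 nearest to their own set. No library was a copy of another in its own group: the chi-square per gene between the closest libraries of a group ran from 228 to 1243. Libraries of different arms, and the cell lines, were not compared in this way.

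Named genes are the 10 largest rises and the 10 largest falls past the threshold that have the same direction in every set (no overlap between groups for 0 h against normal) and a mean of at least 1 CPM. The 12 study genes and the 4 members with the smallest p in each called list are also named. Genes with 0 reads in a group have a bound from 3 reads over the group, and genes with 1 to 3 reads have a ratio with a 95% interval for counting error in the pooled reads. Lists were tested by camera with a correlation of 0.01, again with an estimated correlation, and by fry, with p adjusted over the 28 lists. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment within 1 list.

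The MEIS2 to CRBN ratio and the 12 study genes were tested by exact two-sided sign-flip tests within sets, and by an exact two-sided permutation test for 0 h against normal. Study gene p was adjusted over the 12 genes, and ratio p over the comparisons. Correlations of effects were compared with all 64 swaps of arm labels within sets.

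The fit was tested on simulated counts drawn from its own fitted means and spread, with changes of 1.5, 2 and 4-fold planted in 200 genes. It found 64.2%, 74.6% and 89.4% of them for lenalidomide against control, with 1 false call of 153, and 0%, 7.5% and 51.5% for control culture against 0 h, with 1 of 40. For 0 h against normal it found 0%, 0% and 25.8%, with 0 of 17. Few genes were changed in the simulation, which makes the adjusted p stricter than in real data with many changes. In the real data 4181 genes were called there, 3871 of them at least 2-fold. The simulated shares therefore do not give the share of true changes missed in the comparisons with 0 h. The rule first written asked for 30% at 4-fold. That rule failed for 0 h against normal and was replaced by a rule asking only that 4-fold changes be found more often than 1.5-fold ones. The median bias ran from -0.082 to 0.07 log2. Genes were drawn independently and every set responded alike, so the shares found and the false calls hold only for data that follow the fitted model.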

Results

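RNA sequencing read counts per gene were compared in 40 human libraries. Of these, 4 came from normal plasma cells, 34 from 7 numbered myeloma sets, and 1 each from the myeloma cell lines MM1.S and KMS12. Every myeloma set was cultured in 4 arms: control culture, lenalidomide, palbociclib (PD0332991, an inhibitor of the kinases CDK4 and CDK6), and palbociclib plus lenalidomide. A library at 0 h was held for 6 of the 7 sets. Reads counted on genes ran from 20.7 to 68.7 M per library (M for 10 to the power of 6; median 48.2 M). Group medians were 49.6 M for normal plasma cells, 49.8 M at 0 h, 43.5 M in control culture, 49.2 M with lenalidomide, 48.0 M with palbociclib and 45.4 M with both drugs. No source used here states that the 7 sets are separate donors, so the p-values measure only the spread between these samples. Gene levels are counts per M (CPM) as group mean ± SD, and log2 differences carry a standard error (SE). Chromosome positions are as the files give them, and the genome build is not given in the sources used here.

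TLR7, MUC1, FCGR2B and several interferon-stimulated genes rose in lenalidomide culture. TLR7, an endosomal receptor for single-stranded RNA, rose 6.18-fold over control culture (log2 2.63 ± 0.50 SE), from 6.47 ± 9.92 to 24.4 ± 21.5 CPM (n = 7, adjusted p = 0.0143). MUC1, a membrane mucin, rose 2.73-fold (log2 1.45 ± 0.20 SE), from 7.89 ± 4.81 to 23.0 ± 17.6 CPM (n = 7, adjusted p = 0.00109). XIRP1, an actin-binding protein of striated muscle, rose by log2 5.09 from a low level, 0.336 ± 0.453 to 17.1 ± 25.9 CPM (adjusted p = 0.0212). FCGR2B, the inhibitory IgG receptor of B cells, rose 2.17-fold, from 64.4 ± 54.9 to 157 ± 163 CPM (adjusted p = 0.00343), although its reads are hard to tell from those of its near copy FCGR2C. RNASE1, a secreted ribonuclease, rose 3.69-fold, HHLA2, a B7-family ligand, 3.60-fold, and ST14, a membrane serine protease, 3.27-fold. MAGEC3, a cancer-testis antigen, TRIM6, a ubiquitin ligase of the interferon response, and ST7OT1, a transcript overlapping ST7, rose by log2 1.40, 1.34 and 1.63. Each of these 10 genes was higher in 7 of 7 sets, which the rule for naming them required.

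Among the genes that fell with lenalidomide, CELSR2, an adhesion cadherin, went down 4.48-fold, from 5.83 to 1.77 CPM (n = 7, adjusted p = 0.0115). SCNN1B, a sodium channel subunit, fell with log2 -1.69, ITGA8, an integrin subunit, with log2 -1.65 and SYNGR3, a synaptic vesicle protein, with log2 -1.23. TNFRSF13C, the BAFF receptor of B cells, fell with log2 -1.11 (adjusted p = 0.0115), and GFI1, a transcriptional repressor of blood cell development, with log2 -0.83 (adjusted p = 0.0359). DCPS, an mRNA cap scavenger enzyme, fell from 12.7 to 6.87 CPM, log2 -0.94 ± 0.12 SE (adjusted p = 0.000531). The pseudogene ANKRD36BP2 (log2 -1.34, adjusted p = 0.000688), the carnosine synthase CARNS1 (log2 -1.08) and the kinase-like gene RPS6KL1 (log2 -1.01) complete the 10 largest falls. All 10 were lower in 7 of 7 sets, again as the naming rule required.

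The interferon-stimulated genes were the gene group with the clearest shift under lenalidomide. Of 42 measured members 4 rose and 0 fell, with 38 not called, while 14 rose when p was adjusted over the list alone, and the median log2 difference was 0.30 (n = 7 sets). IFITM2, a membrane restriction factor, rose 2.12-fold, from 38.4 to 81.1 CPM (adjusted p = 0.00377). Its neighbours IFITM3 and IFITM1, which share much of its sequence, rose by log2 0.87 and 0.97 in 6 of 7 sets each, and PLSCR1, a scramblase induced by interferon, by log2 0.55 in 7 of 7. The list test gave adjusted p = 2.39e-15, and adjusted p = 1 with an estimated correlation. B cell markers (17 measured, median log2 -0.44, 0 called, 5 lower when adjusted over the list alone) gave adjusted p = 0.00139, and adjusted p = 1 with an estimated correlation. Plasma cell identity genes (20 measured, median log2 -0.14, 0 called, 2 higher and 4 lower when adjusted over the list alone) gave adjusted p = 0.0429, and adjusted p = 1 with an estimated correlation. Markers of megakaryocytes and platelets (11 measured, median log2 0.31, 0 called) gave adjusted p = 0.0408, and adjusted p = 1 with an estimated correlation. The mean of the stromal cell markers was higher in 5 of 7 sets, by log2 0.12 ± 0.40 SD (exact two-sided sign-flip p = 0.453, smallest possible p = 0.0156).

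In all, 97 genes rose and 63 fell with lenalidomide among 17781 tested (edgeR quasi-likelihood test with the set as a block, Benjamini-Hochberg adjustment). Of these 160 genes, 83 moved the same way in all 7 sets and 54 moved at least 2-fold. Unadjusted p was under 0.05 for 2018 genes where 889 are expected by chance. DESeq2 called 391 genes. Without the set as a block 0 genes were called, and with only the 2 compared arms in the fit 4 were. Leaving out 1 set gave 28 to 508 calls, of which 39.4% to 78.6% were rises, so the balance of rises and falls turns with the sets used.

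Palbociclib alone left 0 of 17781 genes past the threshold against control culture. The genes of its target kinases were at similar levels: CDK4 1.08-fold its control level, and CDK6 at 238 ± 82.1 against 217 ± 70.8 (n = 7). RB1, the target of both kinases, was at 55.5 ± 26.7 against 55.8 ± 29.4 CPM. The smallest adjusted p of any gene was 0.244 (edgeR quasi-likelihood test). Unadjusted p was under 0.05 for 970 genes, 889 being expected by chance, and DESeq2 called 10 genes. Simulated 2-fold changes were found in 74.6% of cases in the same fit with lenalidomide and control libraries, so the absence of calls does not exclude smaller or less regular changes.

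Groups of genes shifted under palbociclib in the list test, while 0 of their members were called. Genes of G2 and mitosis (38 measured) had a median log2 difference of -0.11, adjusted p = 2.68e-05, and adjusted p = 0.719 with an estimated correlation. Genes of E2F and S phase (52 measured, 2 lower when adjusted over the list alone) had a median of -0.07, adjusted p = 0.0214, and adjusted p = 0.745 with an estimated correlation. Ribosomal protein genes (41 measured) were higher, median 0.08, adjusted p = 1e-05, and adjusted p = 0.452 with an estimated correlation. Markers of B cells had a median of -0.37 (1 lower when adjusted over the list alone), adjusted p = 2.68e-05, and adjusted p = 0.452 with an estimated correlation. Neutrophil markers (16 measured, 6 lower when adjusted over the list alone) had a median of -0.94, adjusted p = 0.00114, and adjusted p = 0.719 with an estimated correlation. NK cell markers (9 measured) had a median of -0.52, adjusted p = 0.0079, and adjusted p = 0.452 with an estimated correlation. For monocyte markers (22 measured, median -0.27) adjusted p = 0.0303, for megakaryocyte markers (median -0.53) 0.0323, for cholesterol synthesis genes (23 measured, median -0.08) 0.0476 and for plasma cell identity genes (median -0.12) 0.034. In these 4 lists adjusted p = 0.719 with an estimated correlation. CDK4/6 and RB pathway genes (22 measured, 0 called, 2 lower when adjusted over the list alone, median -0.02) gave adjusted p = 0.629.

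With both drugs, TLR7 again rose, by log2 2.64 over control culture, next to SLC6A12, PDGFRA and CHI3L1. SLC6A12, a betaine and GABA transporter, rose 9.35-fold (log2 3.23 ± 0.45 SE), from 0.809 ± 1.31 to 7.20 ± 9.82 CPM (n = 7, adjusted p = 0.00068). PDGFRA, a platelet-derived growth factor receptor, rose 4.70-fold, from 1.56 to 9.02 CPM (adjusted p = 0.00147), and CHI3L1, a secreted chitinase-like protein, 4.49-fold. RNASE1, ST14, HHLA2, TRIM6 and ST7OT1 also rose, the last 4 by log2 1.52, 1.55, 1.56 and 1.55, and PLA2G4C, a phospholipase, by 1.47. PTPRCAP, which binds the leukocyte phosphatase CD45, fell 3.30-fold, from 56.3 ± 46.7 to 15.2 ± 9.81 CPM (n = 7, adjusted p = 0.000844). CPNE5, a calcium-binding copine, fell from 97.7 to 36.1 CPM (log2 -1.64), and CELSR2 fell 4.91-fold (adjusted p = 0.0037). ITGA8, SCNN1B, RPS6KL1, SYNGR3 and ANKRD36BP2 fell with log2 -1.93, -1.73, -1.32, -1.30 and -1.29, as did TMEM74 (log2 -1.35), a lysosomal membrane protein, and the receptor pseudogene OR2A20P (log2 -1.27).

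Interferon-stimulated genes rose with both drugs as a group, with 11 of 42 measured members up, 0 down and 31 not called (median log2 0.49), and 20 up when adjusted over the list alone. OAS3, a double-stranded RNA sensor, rose by log2 1.25 (adjusted p = 0.0119, 6 of 7 sets), PLSCR1 by 0.61, IFITM2 by 0.89 and IFITM3 by 0.77. The list gave adjusted p = 1.49e-15, and adjusted p = 0.523 with an estimated correlation. B cell markers fell in 4 of 17 members (8 when adjusted over the list alone, median log2 -0.62): FCER2, the low-affinity IgE receptor CD23, with log2 -1.17, SPIB, a B lineage transcription factor, with -0.93, CD79B, a B cell receptor chain, with -0.87, and CD37, a tetraspanin, with -0.55. The list gave adjusted p = 4.57e-05, and adjusted p = 0.523 with an estimated correlation. Plasma cell identity genes fell in 5 of 20 members, with 0 up (2 up and 11 down when adjusted over the list alone, median log2 -0.34). POU2AF1, a B lineage coactivator, went from 407 to 249.5 CPM (log2 -0.82, adjusted p = 0.0134), and MZB1, an endoplasmic reticulum chaperone of antibody secretion, from 396 ± 294 to 242 ± 152 CPM (log2 -0.64). TNFRSF13B, the receptor TACI, fell with log2 -0.93, and FKBP11, a peptidyl-prolyl isomerase, with -0.39. This list gave adjusted p = 0.000138, and adjusted p = 0.523 with an estimated correlation.

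Other group shifts were also measured with both drugs. Oxidative phosphorylation genes (30 measured, 2 down, 3 when adjusted over the list alone) had a median log2 difference of -0.10, with NDUFV1 and NDUFB8 of complex I at -0.21 and -0.22. That list gave adjusted p = 0.000955, and adjusted p = 0.523 with an estimated correlation. NK cell markers (2 of 9 down, 4 when adjusted over the list alone, median -0.82), among them the granzyme GZMH (log2 -1.05) and FGFBP2 (log2 -1.93), gave adjusted p = 0.0357, and adjusted p = 0.523 with an estimated correlation. Genes of G2 and mitosis (1 of 38 down, the mitotic kinesin KIF20A with log2 -0.47; median -0.09) gave adjusted p = 0.0346, and adjusted p = 0.908 with an estimated correlation. Among CDK4/6 and RB pathway genes, CDKN1A, an inhibitor of cyclin-dependent kinases, rose by log2 0.52, and E2F2, an activator of S phase, and CDKN2C, an inhibitor of CDK4 and CDK6, fell with -1.01 and -0.56. With 19 of the 22 not called, that list had a median of 0.06, a mean of -0.02 and adjusted p = 0.707. In all, 205 genes rose and 387 fell among 17781 (edgeR quasi-likelihood test with the set as a block, n = 7), 423 of them with the same sign in all 7 sets. Unadjusted p was under 0.05 for 3270 genes, and without the set as a block 0 genes were called. Leaving out 1 set gave 153 to 999 calls, and DESeq2 gave 1121. Immunoglobulin genes held a median of 16.2% of gene counts in control culture, 13.3% with lenalidomide, 15.9% with palbociclib and 10.6% with both drugs. Apart from the stromal marker score, the mix of cells was not tested in the drug arms. The changes in the drug comparisons, and the absence of calls with palbociclib, thus cannot be assigned to the myeloma cells alone.

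Lenalidomide added to palbociclib moved many of the genes that it moved alone. XIRP1 rose 37.1-fold against palbociclib alone (log2 5.21, adjusted p = 0.0124) and TLR7 7.06-fold (log2 2.82, adjusted p = 0.00775). SLC6A12, CHI3L1, PDGFRA, RNASE1 and ST14 rose by log2 2.84, 2.52, 2.36, 1.90 and 1.69. VAMP5, a vesicle fusion protein (log2 1.73), MYO1G, a myosin of blood cells (log2 1.68), and HSPA7, a heat shock pseudogene close in sequence to HSPA6 (log2 1.92), also rose. CELSR2, UTS2R, a urotensin receptor, CPNE5 and SYNGR3 fell with log2 -2.09, -1.57, -1.43 and -1.42. NPAS1, a transcription factor, RASSF6, a Ras-association protein, RPS6KL1 and PTPRCAP fell with -1.32, -1.27, -1.24 and -1.20. OR2A20P (log2 -1.14) and MEF2B, a germinal centre transcription factor (log2 -1.02), also fell.

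Of 42 interferon-stimulated genes 8 rose, 0 fell and 34 were not called in this comparison (26 rose when adjusted over the list alone, median log2 0.58). XAF1, an interferon-induced apoptosis factor, rose by log2 1.03 (adjusted p = 0.0133), OAS3 by 1.30 (adjusted p = 0.0143), IFITM2 by 0.94 and PLSCR1 by 0.65. The list gave adjusted p = 2.5e-24, and adjusted p = 0.601 with an estimated correlation. Plasma cell identity genes (1 of 20 down, FKBP11 with log2 -0.43; 2 up and 4 down when adjusted over the list alone, median -0.20) gave adjusted p = 0.0088, and adjusted p = 0.819 with an estimated correlation. Monocyte markers (1 of 22 up, the lysozyme gene LYZ with log2 0.69 in 5 of 7 sets; median 0.23) gave adjusted p = 0.00613, and megakaryocyte markers (0 called, median 0.37) gave 0.0305, each at adjusted p = 0.819 with an estimated correlation. Ribosomal protein genes (0 called, median -0.07) gave adjusted p = 0.000566 and oxidative phosphorylation genes (0 called, median -0.06) gave 0.021. In both lists adjusted p = 0.819 with an estimated correlation. In all, 118 genes rose and 64 fell among 17781 (edgeR quasi-likelihood test with the set as a block, n = 7), 134 of them with the same sign in all 7 sets, and 2089 had unadjusted p under 0.05. Without the set as a block 0 genes were called. Leaving out 1 set gave 46 to 378 calls, of which 45.2% to 76.5% were rises.

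The lenalidomide effect with and without palbociclib comes from separate libraries, so the genes can be laid side by side. TLR7, RNASE1 and ST14 are among 66 genes that rose in both, and CELSR2, SYNGR3 and RPS6KL1 are among 33 that fell in both. If the calls of each comparison were independent, 0.644 and 0.227 genes would be shared. Both comparisons come from the same fit, with the same sets and the same spread estimate per gene, so independence cannot be assumed. The number shared by chance in such a fit was not measured. Of the 160 genes called with lenalidomide alone, 159 had the same sign with palbociclib present (99.4%), against 66.3% of all tested genes, and 182 of 182 held in reverse. Across genes the log2 differences had Pearson r = 0.523 (Spearman 0.444), and r = 0.728 for genes with a mean of at least 5 CPM. When arm labels were swapped within sets, 1 of 64 swaps, the real one, gave so large a value in each case. The highest other was 0.499 for all tested genes and 0.698 for genes with a mean of at least 5 CPM.

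**Figure D1:**
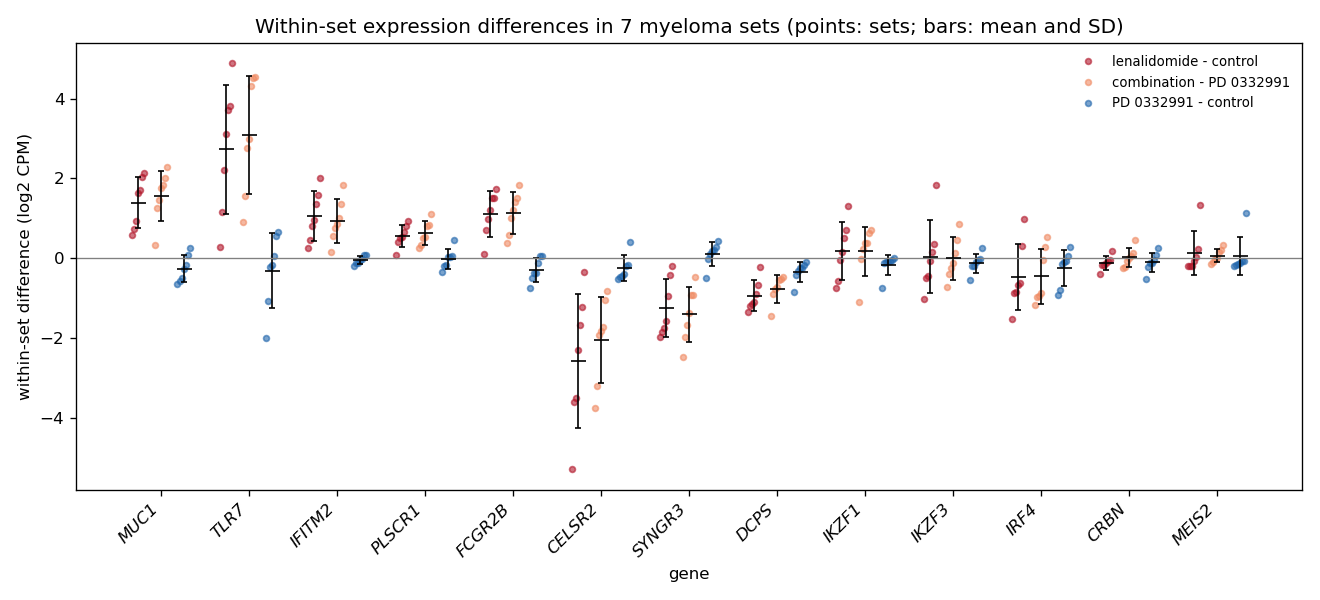
Within-set log2 differences for named genes with lenalidomide against control, both drugs against palbociclib, and palbociclib (PD0332991 in the key) against control. Points are the 7 sets, and bars give the mean and SD.

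Palbociclib added to lenalidomide left 0 of 17781 genes past the threshold (edgeR quasi-likelihood test, smallest adjusted p = 0.399, n = 7 sets). Unadjusted p was under 0.05 for 740 genes, 889 being expected by chance, and DESeq2 called 3. Cholesterol synthesis genes, G2 and mitosis genes and oxidative phosphorylation genes were lower as lists (adjusted p = 0.000759, 0.000759 and 0.000414, with 0 members called in each). For these, adjusted p = 0.595, 0.790 and 0.595 with an estimated correlation. Plasma cell identity genes (adjusted p = 0.00307), unfolded protein response genes (0.0162, with 5 lower when adjusted over the list alone) and glycolysis genes (0.0324) were also lower as lists, each at adjusted p = 0.595 with an estimated correlation. So were the markers of neutrophils (adjusted p = 0.00633, median log2 -0.50), NK cells (0.00633, median -0.44), T cells (0.0106), megakaryocytes (0.0162) and B cells (0.0444). For neutrophil, NK cell and T cell markers adjusted p = 0.595 with an estimated correlation, for megakaryocyte markers 0.703 and for B cell markers 0.750. The effect of palbociclib with lenalidomide, set against its effect without it, had Pearson r = 0.219 across genes (Spearman 0.280), and 5 of 64 swaps gave as large a value, the highest other being 0.264.

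The lenalidomide effect was also tested directly for a difference between cultures with and without palbociclib. No gene was called: 0 of 17781 passed (edgeR quasi-likelihood test, smallest adjusted p = 1, n = 7), and DESeq2 called 0. Unadjusted p was under 0.05 for 288 genes, 889 being expected by chance. Why the count lies below chance was not tested, so a test too strict for this comparison is not excluded. TLR7 and MUC1 were among the genes whose lenalidomide effect was not called different. No interaction was simulated, so how large a difference this test would find is not known. Ribosomal protein genes had a lower median interaction, log2 -0.10 over 41 genes, with 0 called. The list gave adjusted p = 1.52e-07, and adjusted p = 0.728 with an estimated correlation.

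MEIS2, a homeobox transcription factor that binds cereblon, and CRBN, the gene of cereblon, the lenalidomide target, had a ratio that passed no test in any comparison. MEIS2 was at 14.8 ± 6.53 CPM in control culture, 15.1 ± 3.79 with lenalidomide, 14.3 ± 4.21 with palbociclib and 15.4 ± 4.64 with both (n = 7). CRBN was at 28.3 ± 4.63, 26.8 ± 3.81, 26.8 ± 3.55 and 27.9 ± 3.07 CPM. The log2 MEIS2 to CRBN ratio was -1.10 ± 0.76 in control culture, -0.96 ± 0.61 with palbociclib, -0.85 ± 0.47 with lenalidomide and -0.91 ± 0.48 with both drugs. With palbociclib the ratio was higher by 0.14 ± 0.36 SD in log2 (5 of 7 sets higher, exact two-sided sign-flip p = 0.391). With lenalidomide the difference was 0.25 ± 0.42 SD (5 of 7 sets, exact p = 0.0938) and with both drugs 0.19 ± 0.33 SD (4 of 7 sets, exact p = 0.219). Both drugs against palbociclib gave 0.05 ± 0.31 SD (2 of 7 sets higher and 5 lower, exact p = 0.703) and both drugs against lenalidomide -0.06 ± 0.22 SD (4 of 7 sets higher, exact p = 0.516). The smallest possible p with 7 sets is 0.0156. Leaving out 1 set gave differences of 0.02 to 0.19 with palbociclib, 0.10 to 0.31 with lenalidomide and 0.10 to 0.25 with both drugs. For both drugs against palbociclib the sign turned, at -0.04 to 0.10, and both drugs against lenalidomide reached 0, at -0.10 to 0.00. MEIS2 has Entrez ID 4212 and lies on chromosome 15 from 37183232 to 37393500, and CRBN has Entrez ID 51185 and lies on chromosome 3 from 3191317 to 3221401.

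**Figure D2:**
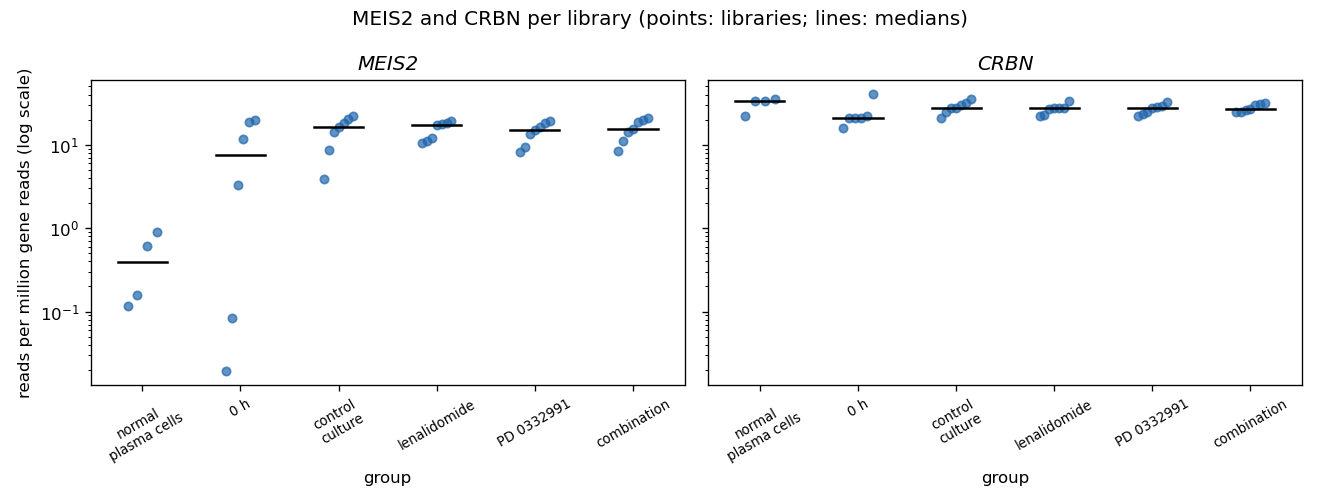
MEIS2 and CRBN levels by group on a log scale. Points are libraries and lines are group medians.

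Neither control culture against 0 h nor myeloma at 0 h against normal plasma cells passed the test of the MEIS2 to CRBN ratio, and the 0 h values varied widely. MEIS2 was at 8.97 ± 9.14 CPM at 0 h (n = 6) and 0.450 ± 0.379 CPM in normal plasma cells (n = 4). CRBN was at 23.6 ± 8.67 and 31.1 ± 5.92 CPM. The log2 ratio in control culture was above 0 h by 2.52 ± 3.86 SD (4 of 6 sets higher, exact two-sided p = 0.219, smallest possible p = 0.0312). Myeloma at 0 h was above normal plasma cells by 2.92 (exact two-sided permutation p = 0.2, smallest possible p = 0.00476), with group means of -3.40 ± 4.11 and -6.32 ± 1.38. Leaving out 1 set or library moved these differences to 1.38 to 3.13 and 2.19 to 4.10. In the cell lines, 1 library each, MEIS2 was at 11.6 CPM in MM1.S and 26.7 CPM in KMS12.

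Of 12 study genes (MEIS2, CRBN, IKZF1, IKZF3, IRF4, MYC, CDK4, CDK6, CCND1, CCND2, CCND3 and RB1), 0 passed the exact test in any drug comparison. The test could hardly pass there: with 7 sets a lone gene at the smallest possible p of 0.0156 has an adjusted p of 0.188, and at least 4 genes would need that p. IRF4, a transcription factor on which myeloma cells depend, differed with both drugs by log2 -0.69 ± 0.68 SD and was lower in 6 of 7 sets (exact two-sided p = 0.0469, adjusted p = 0.281). CCND2, a D-type cyclin, was higher in 7 of 7 sets with both drugs, by log2 0.30 (exact p = 0.0156, adjusted p = 0.188), and in 7 of 7 against palbociclib alone, by log2 0.35 (exact p = 0.0156, adjusted p = 0.188). IKZF1 was lower in 7 of 7 sets with palbociclib, at log2 -0.17 (exact p = 0.0156, adjusted p = 0.188). The lowest set was at -0.75 and the others at -0.12 to -0.004. CDK4 was higher in control culture than at 0 h in 6 of 6 sets, by log2 1.21 ± 0.37 SD (exact p = 0.0312, adjusted p = 0.25), while IRF4 differed by -1.25. IKZF1 and IKZF3, the lymphoid transcription factors degraded through cereblon, were at 127.6 ± 49.0 and 32.0 ± 23.0 CPM in control culture (n = 7). Between 0 h myeloma and normal plasma cells, 3 of the 12 passed: IKZF3 rose by log2 2.10, IRF4 rose by 4.29 and CCND3 fell with log2 -2.95 (each with exact permutation p = 0.00476, adjusted p = 0.0190). IKZF1 differed by log2 -0.69 (exact permutation p = 0.0190, adjusted p = 0.0571).

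Control culture differed from 0 h in stromal markers, cell cycle genes, immediate early genes and plasma cell identity genes. FN1, the matrix protein fibronectin, rose 299-fold, from 5.23 ± 4.51 at 0 h to 1180 ± 619 CPM in control culture (n = 6, adjusted p = 0.00127). FOSB, an immediate early transcription factor, fell 111.5-fold, from 1939 ± 1568 to 13.3 ± 3.36 CPM, and CXCL12, the marrow chemokine, fell 86.6-fold. FOS, of the same transcription factor family, fell with log2 -5.65, RGS1 and RGS2, regulators of G protein signalling, with -5.22 and -4.93, and TSC22D3, a glucocorticoid-induced leucine zipper, with -4.32. C1QB, a complement chain of macrophages, fell with log2 -4.72 and AMPD1, a muscle and plasma cell deaminase, with -4.36, as did the microRNA transcripts MIR27A and MIR23A. Several genes had 0 reads over the group at 0 h and were at least 1106-fold (APCDD1L), 998-fold (PSG2, from a family of near copies), 760-fold (FMN2), 628-fold (PPP4R4), 392-fold (FOXQ1) and 385-fold (GPR1) higher in culture, with the floor set at 3 reads over the group. With 2 or 3 reads at 0 h, MARCH4 had a ratio of 4276 (95% interval 1184 to 35305) and FAM180A one of 2277 (779 to 11040). SPRR2D had a ratio of 1898 (525 to 15671), and IGF2BP1, an RNA-binding protein of fetal tissue, rose by log2 10.47. The intervals of these ratios cover counting error in the pooled reads only, not the spread between samples.

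Cell cycle genes rose as groups in culture. Of 52 E2F and S phase genes 27 rose, 0 fell and 25 were not called (35 rose when adjusted over the list alone, median log2 1.26), with GINS3 up by 3.06 and MCM2 by 2.34, both of the replication helicase. Of 38 G2 and mitosis genes 18 rose (19 when adjusted over the list alone, median 1.51), with the mitotic kinase AURKA up by 3.23 and the ubiquitin conjugase UBE2C by 2.78. Glycolysis and hypoxia genes (28 measured, 13 up and 3 down, median 0.83) included PKM2 (log2 2.48) and ENO1 (log2 2.37) among the rises and PDK1 (log2 -2.36) among the falls. Stromal cell markers (15 measured, 9 up and 1 down, median 3.21) included FN1, THY1 (log2 6.43) and COL1A1 (log2 6.11), while TAGLN was at -1.49. MEIS and PBX family genes (8 measured, 3 up and 1 down, median 1.30) included PBX3, up by 2.54, PBX2, down with -1.02, and MEIS3, with 2 reads at 0 h and a ratio of 202 (95% interval 55.9 to 1667). The lists gave adjusted p = 4.41e-07 (E2F), 5.33e-06 (G2), 0.0154 (glycolysis), 0.00863 (stromal) and 0.0313 (MEIS and PBX). In these 5 lists adjusted p = 0.564 with an estimated correlation.

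Plasma cell and secretory genes fell in culture. Of 20 plasma cell identity genes 16 fell and 1 rose (median log2 -1.47), among them the surface proteins CD38 (log2 -2.27) and SLAMF7 (-2.21) and the folding genes FKBP11 (-2.02) and DERL3 (-2.33). Unfolded protein response genes (27 measured, 16 down and 1 up, median -0.99) included HERPUD1 (log2 -1.95) and MANF (-1.15). Of 41 ribosomal protein genes 28 fell (median -0.76; RPL15 with -1.35), and of 17 histone genes 3 fell (median -0.69). Immediate early genes (25 measured, 11 down and 3 up, median -1.73) included DUSP1, a phosphatase (log2 -4.27), and KLF2, a zinc finger factor (log2 -3.86). Markers of other blood cells fell too: erythroid (13 of 15, median -1.78; HBB with -1.99), monocyte (9 of 21, 1 up, median -1.35; C1QA with -4.19), B cell (8 of 17, median -1.16; CD79A with -2.01), T cell (4 of 17, 1 up, median -1.16; CD4 with -2.45) and neutrophil (6 of 15, 2 up, median -1.54; MMP9 rose by 3.01). Adjusted p was 5.33e-06 for plasma cell identity and for erythroid markers, 1.82e-07 for ribosomal, 0.000589 for unfolded protein response, 0.00236 for immediate early, 0.0305 for histone and neutrophil, 0.0058 for monocyte, 0.0159 for B cell and 0.0124 for T cell lists. For neutrophil markers adjusted p = 0.591 with an estimated correlation, and for the other 9 lists adjusted p = 0.564 with an estimated correlation. In all, 3364 genes rose and 3014 fell among 16519 tested (edgeR quasi-likelihood test with the set as a block, n = 6), 5386 with the same sign in all 6 sets and 4684 at least 2-fold. Unadjusted p was under 0.05 for 8232 genes. Without the set as a block 3471 genes were called, and leaving out 1 set gave 4110 to 6119. Immunoglobulin genes held a median of 39.8% of gene counts at 0 h (n = 6) and 16.2% in control culture (n = 7), while stromal markers rose. A change in the mix of cells was not tested here, so these shifts cannot be assigned to changes within the myeloma cells.

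Myeloma at 0 h differed from normal plasma cells in MAGEC1, MAGEC2 and DKK1, in plasma cell identity genes and in the markers of other blood cells. MAGEC1 and MAGEC2, cancer-testis antigens of the X chromosome, had 0 reads in the normal group and were at least 5193-fold and 2509-fold higher in myeloma, and NOL4, a nucleolar protein, at least 1495-fold. MAGEC3 had a ratio of 1955 (95% interval 541 to 16142, counting error only). DKK1, a secreted Wnt inhibitor linked to myeloma bone disease, rose 651.5-fold, from 0.136 ± 0.0799 in normal (n = 4) to 89.2 ± 95.8 CPM in myeloma (n = 6, adjusted p = 0.00529). EPHA6, an ephrin receptor, rose by log2 9.66 and FAM133A by 8.96, and the neuronal adhesion gene CNTN5, the Wnt regulator CXXC4 and the glycosyltransferase GALNT13 were also among the 10 largest rises. CAMP, an antimicrobial peptide, CEACAM8, MMP8 and LTF, all of neutrophil granules, fell with log2 -8.11, -8.10, -7.97 and -7.90. NEFL, a neurofilament, was at least 231-fold lower, and the sperm protein CRISP2 had a ratio of 732. LCN2, S100A8 (log2 -6.93) and DEFA3 fell, with reads of DEFA3 hard to tell from those of DEFA1. Haemoglobin HBA2, close in sequence to HBA1, fell 44.8-fold, from 31780 ± 11330 to 710 ± 1144 CPM.

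Plasma cell identity genes rose in 19 of 20 members (median log2 3.86). POU2AF1 rose 22.0-fold, from 26.9 ± 9.08 to 589 ± 124 CPM (adjusted p = 0.000553), TNFRSF17, the receptor BCMA, by log2 5.62, SLAMF7 by 4.80 and IRF4 by 4.32. Unfolded protein response genes (21 of 27 up, median 2.58) included DNAJB9 (log2 3.75), HSP90B1 (3.17) and PDIA4 (3.14). Cholesterol synthesis genes (24 measured, 8 up, median 0.70) included PMVK, a mevalonate pathway kinase (log2 1.73). The lists gave adjusted p = 5.49e-15 (plasma cell identity), 3.97e-12 (unfolded protein response) and 0.0426 (cholesterol). These were adjusted p = 0.188, 0.215 and 0.362 with an estimated correlation. Chemokine and cytokine genes (24 measured, 5 down, median -1.15) gave adjusted p = 0.000498, and adjusted p = 0.378 with an estimated correlation.

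Proliferation genes fell in myeloma at 0 h. Of 52 E2F and S phase genes 32 fell (43 when adjusted over the list alone, median log2 -1.52; TK1 with -2.32 and MCM4 with -2.29), and of 38 G2 and mitosis genes 23 fell (32 when adjusted over the list alone, median -1.98; CDC20 with -3.38). Markers of other cell types fell as well: neutrophil (15 of 16, median -7.59), T cell (15 of 18, median -4.68; BCL11B with -5.53 and CD6 with -5.39), erythroid (10, median -4.17; KLF1 with -4.65), NK cell (7 of 15, median -3.39; NKG7 with -4.94), endothelial (3 of 10, median -2.97), megakaryocyte (4, median -2.90; TUBB1 with -2.69), monocyte (5, median -2.54) and stromal (2 of 17, median -2.04; IGFBP7 with -3.90). Adjusted p was 1.44e-12 for E2F, 1.52e-11 for G2, 2.34e-10 for neutrophil, 9.03e-10 for T cell, 2.67e-08 for erythroid, 1.18e-06 for NK cell, 7.25e-07 for monocyte, 8.06e-05 for megakaryocyte, 0.00105 for endothelial and 0.000499 for stromal lists. For stromal markers adjusted p = 0.41 with an estimated correlation, and for the other 9 of these lists adjusted p = 0.362 with an estimated correlation. Globin genes held 14.2% of gene counts (median) in normal plasma cell libraries and 0.0932% in myeloma at 0 h, and immunoglobulin genes 3.79% and 39.8%. Globin genes are among the erythroid markers, so the normal libraries held many reads of genes listed for other blood cells. Differences in this comparison, those of plasma cell identity, proliferation and study genes included, cannot be assigned to plasma cells alone. In all, 2355 genes rose and 1826 fell among 17404 tested (edgeR quasi-likelihood test without a block, n = 6 and n = 4). Of these 3341 had no overlap between the groups, where chance gives 0.952% of genes not chosen by a test, 3871 moved at least 2-fold, and 6862 had unadjusted p under 0.05. Leaving out any 1 normal library gave 2061 to 2557 calls, and leaving out 1 library of either group gave 2061 to 5748.

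Positions of the named genes are given as the files list them. TLR7 lies on chromosome X from 12885202 to 12908480, MUC1 on chromosome 1 from 155158300 to 155162700, CELSR2 on chromosome 1 from 109792641 to 109818378, and XIRP1 on chromosome 3 from 39224707 to 39234077. FCGR2B lies on chromosome 1 from 161632905 to 161648444, IFITM2 on chromosome 11 from 308107 to 309410 and SLC6A12 on chromosome 12 from 299250 to 323371. IKZF1 lies on chromosome 7 from 50344378 to 50472799, IKZF3 on chromosome 17 from 37921198 to 38020441 and IRF4 on chromosome 6 from 391752 to 411443. POU2AF1 lies on chromosome 11 from 111222980 to 111250157, FN1 on chromosome 2 from 216176679 to 216300791 and FOSB on chromosome 19 from 45971253 to 45978437. CXCL12 lies on chromosome 10 from 44865605 to 44880545, DKK1 on chromosome 10 from 54074041 to 54077417 and MAGEC1 on chromosome X from 140991642 to 140997187.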

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

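Tests chosen after the result was seen here are the comparison of lenalidomide calls with the separate palbociclib libraries, the checks of MEIS2 against stromal markers and against 0 h, the check of other cell types in the normal libraries, and the search for genes beyond the plasma cell rise. The fits with a stromal score, with thinned reads and without immunoglobulin and globin genes, and the check of each set's response, were also added after the files were seen. The MEIS2 rule was tightened after its result was seen, to ask for a permutation p under 0.05 as well.

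Lenalidomide arms differ from their controls in 160 genes, TLR7, MUC1 and CELSR2 among them. A regular shift in the stromal marker score was not seen: it was higher in 5 sets and lower in 2, by log2 0.12 ± 0.40 SD (exact two-sided sign-flip p = 0.453). With that score in the fit 91.2% of the 160 calls stay. Among 17781 genes in that fit, 1694 followed the score up and 1204 followed it down. A score that differs so little between arms could remove few calls, so this fit decides little. The shares of other cell types were not tested in this way. A difference in depth is not favoured, since 79.4% stay after every library is thinned to the smallest total. Treatment with lenalidomide is consistent with the signs: 99.4% of the calls have the same sign in the separate libraries with palbociclib. Of the marker list, 8 of 18 stromal genes reach 1 CPM in a myeloma cell line, so the score is not specific to stromal cells.

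MEIS2 in culture could come from the myeloma cells or from other cells that grow. Within sets, MEIS2 follows the stromal marker score with r = 0.53 over 28 libraries (permutation p adjusted over MEIS2 and CRBN 0.140) and Spearman 0.576 (permutation p = 0.00397). Pearson r is 0.45 without the 2 farthest libraries and 0.591 without the set of the farthest library, CRBN gives 0.0840, and MEIS2 stands at the 90.7th percentile of genes, so stromal reads cannot be told from myeloma reads here. The reading that MEIS2 reads come from the myeloma cells already there at 0 h does not hold in every set: control culture is over 4-fold above 0 h in 2 of 6 sets, which had at most 4 reads at 0 h. In the other 4 sets the cultured level is within 2-fold of 0 h, so there that reading stays open.

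Myeloma at 0 h differs from normal plasma cells in neutrophil, T cell and erythroid markers. How far other cell types in the normal plasma cell libraries carry this is left open: 6 of 6 marker lists have a negative median and at least 1 member lower, which restates the pattern and is no separate test of it. Globin genes, which are erythroid markers, held 10.3% to 20.4% of gene counts in the normal libraries, and immunoglobulin genes 2.85% to 6.48%. At 0 h globin genes held at most 2.74% and immunoglobulin genes 18.2% to 59.0%, so the 2 groups did not overlap in either share. Reads of erythroid genes were thus present in every normal library, and other cell types carry at least the erythroid part of the pattern. The differences in proliferation genes, IRF4, IKZF3 and CCND3 cannot be read as myeloma against normal plasma cells alone. Leaving out immunoglobulin and globin genes gave 4198 calls against 4181. TMM scaling already limits the weight of such genes in the chosen fit, so this near match decides little about their share. Whether myeloma plasma cells express genes that normal plasma cells do not is left open: 57 genes such as MAGEC1 rise beyond the largest rise of the plasma cell list, and 2 do so by over 2 standard errors.

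Swapping arm labels within sets compares the real count of calls with counts under chance labels. The fitted trend of the spread was kept from the real labels. For lenalidomide 2 of 64 swaps give as many calls as the real 160, which is under 1 in 20, the highest other giving 314. With 8 comparisons tried and no adjustment over them, chance is not excluded there. For both drugs against control 1 of 64 does (real 592, highest other 120) and for both drugs against palbociclib 1 of 64 (real 182, highest other 47). For control culture against 0 h 1 of 32 does (real 6378, highest other 0). In these 3 the real labels gave the most calls, the smallest share such swaps can give, again without adjustment. For 0 h against normal 1 of 100 splits does (real 4181, highest other 2205), so the real count was the highest, although other splits reach large counts. For palbociclib against control 64 of 64 do (real 0, highest other 1), for both drugs against lenalidomide 64 of 64 (real 0, highest other 0) and for the interaction 64 of 64 (real 0, highest other 0). A real count of 0 makes that outcome certain, so in these 3 the swaps test nothing and chance cannot be excluded by them.

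The lenalidomide swap with 314 calls exchanges the arms of 1 set only. Each set was compared with the others over the genes called for both drugs against control without it, 997 genes for this set, with the signs of that comparison, so the genes differ between sets. In this set 39.6% of them have that sign with lenalidomide, against 64.3% to 91.8% elsewhere, and 65.2% with both drugs, against 79.3% to 93.5%. It does not stand alone in every comparison: with both drugs against palbociclib it has 63.5%, where another set is lower at 47.3%, and with both drugs against lenalidomide it has 73.1%. That other set has 39.5% with both drugs against lenalidomide. Its median log2 difference along the called signs was 0.36 with palbociclib, against at most 0.14 elsewhere. Leaving it out gave 378 calls for both drugs against palbociclib, against 182. Mixed or exchanged libraries were not tested for it. The set of the 314-call swap has the shallowest cultured libraries, with 20.7 to 25.7 M gene reads against at least 39.7 M elsewhere. They also have the highest shares of intron reads (17.1% to 17.6%) and globin reads (up to 0.973%). A weak response, shallow or mixed libraries, or exchanged libraries might give this, and none was established: thinning every library to the smallest total keeps 79.4% of the lenalidomide calls, which does not test this set. Keeping the set, as here, gives 160 calls, and leaving it out gives 508, with 39.4% rises against 60.6%.

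Single libraries or sets stood apart in 19 of 82 groups of values, where chance gives about 1 in 20 groups. Of 52 groups of differences 12 did so, 9 of them from the same set. With lenalidomide, the log2 ratio difference that stood apart was 1.15 (others -0.12 to 0.30), MEIS2 1.34 (others -0.19 to 0.24) and CDK4 0.64 (others -0.23 to 0.04). With palbociclib, the values that stood apart were MEIS2 1.13 (others -0.20 to -0.07), IKZF1 -0.75 (others -0.12 to 0.00), MYC 0.53 (others -0.15 to 0.13), CDK4 0.64 (others -0.02 to 0.13), CCND1 1.17 (others -0.09 to 0.14) and CCND2 -0.43 (others -0.07 to 0.15). With both drugs, IKZF1 was at -1.16 (others -0.14 to 0.56) and CDK4 at 0.42 (others -0.12 to 0.09), and MYC in culture against 0 h was at 3.64 (others -0.93 to 0.50). The share of globin reads was 0.973% in 1 control library (others 0.00253% to 0.305%), 0.608% with lenalidomide (others up to 0.218%), 0.7998% with palbociclib (others up to 0.215%) and 2.74% at 0 h (others up to 0.117%). The share of immunoglobulin reads was 32.8% in 1 lenalidomide library (others 10.1% to 14.2%) and 35.6% with palbociclib (others 9.82% to 17.3%), and 18482 genes were detected in 1 library with both drugs (others 19301 to 19775). MEIS2 was at 11.6 CPM in MM1.S and 26.7 CPM in KMS12, where the highest normal library had 0.905 CPM.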

How the results depend on the processing

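Genes called, against 160, 0, 592, 182, 0, 0, 6378 and 4181 in the chosen fits, changed as follows, and the cause was not tested. With no replicate block, lenalidomide, both drugs, and both drugs against palbociclib gave 0 genes each and control culture against 0 h gave 3471, so each drug call rests on treating the arms of 1 set as matched. With only the 2 groups compared in the fit, lenalidomide gave 4, both drugs 292, and both drugs against palbociclib 54. DESeq2 gave 391 for lenalidomide, 10 for palbociclib, 1121 for both drugs, 469 for both drugs against palbociclib and 3 for both drugs against lenalidomide. Rises were 50.1% of the lenalidomide calls with DESeq2, against 60.6%. With all 34 myeloma libraries in the fit, control culture against 0 h gave 11311, and with all libraries but the cell lines 0 h against normal gave 7034. With the stromal marker score beside the replicate block, both drugs gave 1484, both drugs against palbociclib 392 and both drugs against lenalidomide 4.

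Gene lists called were 4, 10, 6, 6, 11, 1, 15 and 15. With an estimated correlation 0 were called in each of the 8 comparisons. The fry test called 0 in lenalidomide, palbociclib, both drugs, both drugs against each drug, and the interaction. With no replicate block the lists called were 1 for lenalidomide, 5 for palbociclib, 1 for both drugs against palbociclib, 7 for both drugs against lenalidomide and 8 for control culture against 0 h.

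Leaving out 1 set at a time gave 28 to 508 genes for lenalidomide, 0 to 1 for palbociclib, 153 to 999 for both drugs, 46 to 378 for both drugs against palbociclib and 4110 to 6119 for control culture against 0 h. Rises were 39.4% to 78.6% of the lenalidomide calls and 45.2% to 76.5% of those for both drugs against palbociclib, so the majority turned to falls in 1 case each. Leaving out 1 library gave 2061 to 5748 for 0 h against normal, where any normal library left out gave 2061 to 2557, and 3 to 5 study genes past the exact test. Among named genes past the threshold no direction reversed under any setting. The largest rises and falls were named only if their direction was shared by every set, which favours that outcome. Study genes that were not past it changed sign under some settings, MEIS2 with lenalidomide and with palbociclib among them. RLE scaling moved the median log2 difference of 0 h against normal by -0.122, and TRIM6 lost its call with lenalidomide.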

Other observations

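The genes in this section were chosen after their values were seen. The cell lines, with 1 library each, give levels without a test, and intervals are exact Poisson 95% intervals. MEIS2 was at 11.6 CPM (10.8 to 12.5) in MM1.S and 26.7 CPM (25.3 to 28.1) in KMS12, CRBN at 25.0 and 33.6 CPM, and the MEIS2 to CRBN ratio at 0.465 and 0.794. IKZF1 was at 132 and 26.7 CPM. CCND2 was at 1826 CPM in MM1.S and 1.65 in KMS12, and CCND1 at 21.9 and 646 CPM. MAGEC2 was at 263 CPM in KMS12. FN1 was at 116 and 1034 CPM, so the stromal marker list holds genes that myeloma cells themselves express, while COL1A1 was at 0.452 and 0.0716 CPM. DKK1 was at 1.79 CPM in MM1.S and had 0 reads in KMS12 (up to 0.0660 CPM).

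Single genes of apoptosis and of cytokine signalling rose with lenalidomide, while their lists were not called. Of the BCL2 family 2 of 15 genes rose and 13 were not called (list adjusted p = 0.134), and of chemokines and cytokines 1 of 29 rose and 28 were not called (list adjusted p = 0.999). BMF, a BH3-only activator of cell death, rose by log2 0.92 with lenalidomide (adjusted p = 0.0445), 0.82 with both drugs (adjusted p = 0.0389) and 0.92 with both drugs against palbociclib (adjusted p = 0.0415), in 6 of 7 sets each. BCL2L2, a survival protein of the BCL2 family, rose by log2 0.43, 0.41 and 0.40 in 7 of 7 sets each. LAP3, a leucine aminopeptidase induced by interferon, rose 2.02-fold with lenalidomide, from 80.5 ± 46.9 to 152 ± 70.3 CPM (n = 7). CXCL9, a chemokine induced by interferon gamma, rose by log2 2.37 with lenalidomide (adjusted p = 0.00518) in 6 of 7 sets, from a level carried by few libraries (8.14 ± 21.4 to 53.9 ± 142 CPM).

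Of 24 chemokine and cytokine genes 13 rose, 6 fell and 5 were not called in control culture against 0 h, and the list was not called (adjusted p = 0.0676, and adjusted p = 0.564 with an estimated correlation). CXCL5, a neutrophil chemokine, rose 159-fold (adjusted p = 0.000285), CCL2, a monocyte chemokine, 40.4-fold, IL6, a growth factor for myeloma cells, 39.8-fold, IL1B 68.1-fold and IL8 by log2 4.91, each in 6 of 6 sets. The chemokines CCL3 and CCL4 fell 4.85-fold and 5.55-fold, in 5 of 6 sets each. Of 15 BCL2 family genes 2 rose, 4 fell and 9 were not called (list adjusted p = 0.472). The survival genes MCL1 and BCL2 fell 3.13-fold and 3.54-fold, and BCL2L11, which encodes BIM, fell 3.79-fold, in 6 of 6 sets. Against normal plasma cells, BCL2L11 rose 4.36-fold and BCL2 5.50-fold in myeloma at 0 h. Marker genes of other cells also differed in both comparisons, so these changes cannot be assigned to myeloma cells alone.

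A shift in the cells of the culture could carry MEIS2, given r = 0.53 between MEIS2 and the stromal marker score within sets. Counting MEIS2 reads in sorted CD138-positive and CD138-negative cells of the same culture would tell stromal from myeloma reads.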
